A study of Mus musculus with 2 samples.

How the data were processed

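RNA was taken from pooled lenses of wild-type C57BL/6 mice at postnatal day 7 (P7) and postnatal day 60 (P60), and each pool was hybridised to 1 array. Per the labels' protocols, total RNA was treated with DNase, extracted on spin columns, checked for quality and labelled with biotin after linear amplification. How many animals or eyes entered each pool, their sex and the hour of collection are not given in the sources used here. The values come from a mouse Affymetrix array of 45101 probe sets, each a group of short probes for 1 transcript.

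The deposited values are signal intensities on a linear scale, 1 per probe set and array, and MAS5 is named per the submitters' processing notes. MAS5 combines perfect-match and mismatch probes into a signal and scales every array to a common trimmed mean. The deposited intensities fit that scaling: without the lowest and highest 2% of probe sets, their mean was 499.8 on both arrays. The software version, the scaling settings and the present or absent calls are not given in the sources used here, and no scanner values were used.

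Probe sets were named through a platform annotation table. A single gene symbol was given for 34958 probe sets, several symbols for 932 and none for 9211. Of the 34958, 34754 matched a current mouse gene by gene number, and the table's symbol was kept for the others. Only probe sets with 1 symbol named a gene, and these covered 18194 genes. No genome build is attached to the values, so no coordinates are printed. Gene symbols, the floor, the gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined, with the exceptions named below.

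For each gene the probe set with the highest mean log2 intensity over both arrays was used. The floor was to be the 95th percentile of probe sets for olfactory, vomeronasal and taste receptors, genes not expected in lens, provided that at least 100 such probe sets were named. Only 83 were, so the planned fallback applied, the median of all values of both arrays, which was 103.9. On the P7 array 7 and on the P60 array 9 of these receptor probe sets lay above that floor. A gene counted as measured when its probe set exceeded the floor on at least 1 array. Values under the floor were raised to it before log2 ratios (P60 over P7) were taken, so a fold against such a value is a lower bound and is written "at least".

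With 1 array per age no test between the ages and no p-value is possible, and differences are described by size. A gene was counted as higher or lower from a 2-fold difference on. As a guide to measurement error, the spread of the log2 ratio between probe sets of the same gene was pooled over 4239 genes with 2 or more probe sets above the floor on both arrays. That SD was 0.58. It covers differences between probe sets on the same arrays and leaves out differences between animals, pools and hybridisations. The number of arrays limits the precision of every value.

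For 34 gene lists the median log2 ratio was set against 10000 random lists of the same size, drawn from the measured genes and matched on mean log2 intensity in 20 bins. A list was called apart from matched genes when its percentile was below 2.5 or above 97.5. This was possible for 33 lists with at least 3 measured genes, of which about 1.65 would fall outside these limits by chance if their genes varied independently. Genes of a list can vary together between single pools, so more lists could be called without an effect of age. The percentiles describe these 2 arrays, not the ages at large. The genes named are the 10 with the highest and the 10 with the lowest log2 ratio among genes above the floor on both arrays, with a mean log2 intensity at least 1 above the floor, the 5 in each direction with the highest bound among genes above the floor on 1 array only, every measured crystallin, and the 2 highest and 2 lowest members of each list. Predicted genes and unnamed clones were passed over in the first 2 of these parts.

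The calculation was tested on simulated data made from the P7 values with noise of 0.3 (SD, log2). Of the genes planted at 4-fold, 50 of 50 higher and 50 of 50 lower were counted as changed among 12208 genes, as were 7 of 12008 unchanged genes. That noise is narrower than the SD of 0.58 between probe sets of the same gene. With noise as wide as that SD, 929 of 12440 unchanged genes (7.47%) passed 2-fold, so the smaller count understates what chance can give. At 1.5-fold, 2 of 50 higher and 3 of 50 lower passed the 2-fold limit. Of 1000 random lists of 20 unchanged genes 5% were called, which follows from the limits themselves. All 20 of 20 lists shifted by 0.5 on the log2 scale were called, with the noise of 0.3. The log2 ratios of the measured genes had an SD of 0.90, so such a shift can be missed more often in the real lists. A list that was not called therefore does not exclude a shift of that size.

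The alternatives were other floors, a pseudocount in place of the floor, other scalings (median centring, quantile normalization, loess and centring on ribosomal protein genes), other probe set rules, leaving out the brightest genes, other fold limits and unmatched random lists. Probe sets marking shared sequence were those with names ending in _s_at, _x_at or _a_at. Sequence shared only among transcripts of the same gene (_a_at) was thus left out as well. A floor at the 95th percentile of the receptor probe sets was added after the data had been seen. So were the further gene lists of the closing section (second endothelial set, fetal growth programme, contractile genes, glucocorticoid-induced genes, clock genes opposite in phase to Dbp and Y-linked genes). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used. Control probe sets and probe sets with several or no gene symbols were kept out of the comparison, and some of them are reported in the closing section.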

Results

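Gene expression was profiled in the mouse lens at 2 ages, P7, when the lens is growing fast, and P60, in the young adult. Each age was represented by RNA from 1 pool of lenses on 1 array, so no value has a replicate and differences are given by size only. The arrays had median intensities of 112.9 at P7 and 93.9 at P60, with upper quartiles of 430.8 and 441.7. At P7, 52.2% of the 45101 probe sets lay above the floor of 103.9, and at P60 47.8%. Across the 19194 probe sets above the floor on both arrays, log2 intensities correlated with r = 0.90, a value across probe sets, which are not independent replicates. The ratio of 5′ to 3′ signal, a sign of RNA and cDNA integrity, was 0.785 at P7 and 0.606 at P60 for beta-actin, 1.40 and 1.29 for Gapdh, and 0.0995 and 0.0262 for the dap spike-in (0.158 and 0.0439 on its older probe sets). All of these ratios were lower at P60, also for the spike-in, which is not lens RNA. On its older probe sets the 5′ and 3′ log2 ratios were -1.87 and -0.03, whereas those of the lys spike-in were 0.23 and 0.03. Probe sets far from the 3′ end may thus read lower at P60 at equal RNA. This limits the counts of lower genes and can set probe sets of a gene apart.

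The comparison asked how the lens transcript profile differs between the growing and the adult lens. Of 13029 measured genes, 1494 (11.5%) were at least 2-fold higher and 1230 (9.44%) at least 2-fold lower at P60, and 10305 (79.1%) did not reach 2-fold on the floored values. Without a floor, over all genes, 2761 were higher and 3627 lower in a setting that also changes the pseudocount and the genes counted. For scale, 615 and 314 of 12440 simulated unchanged genes passed 2-fold upward and downward when the noise was as wide as the spread between probe sets of the same gene (SD 0.58). In that simulation only the P60 values carried added noise, so its excess of upward genes can come from its set-up. The split by direction is therefore not a guide to the real counts. Differences of 8-fold or more were found for 71 genes higher and 50 genes lower at P60. The median log2 ratio was 0.02. Among genes 2-fold higher that had 2 or more measured probe sets, 465 of 692 had every probe set on the higher side, and among those 2-fold lower 396 of 515 had every one on the lower side. The ratio bounds of 240 higher and 342 lower genes rest on a value under the floor at 1 age.

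**Figure D1:**
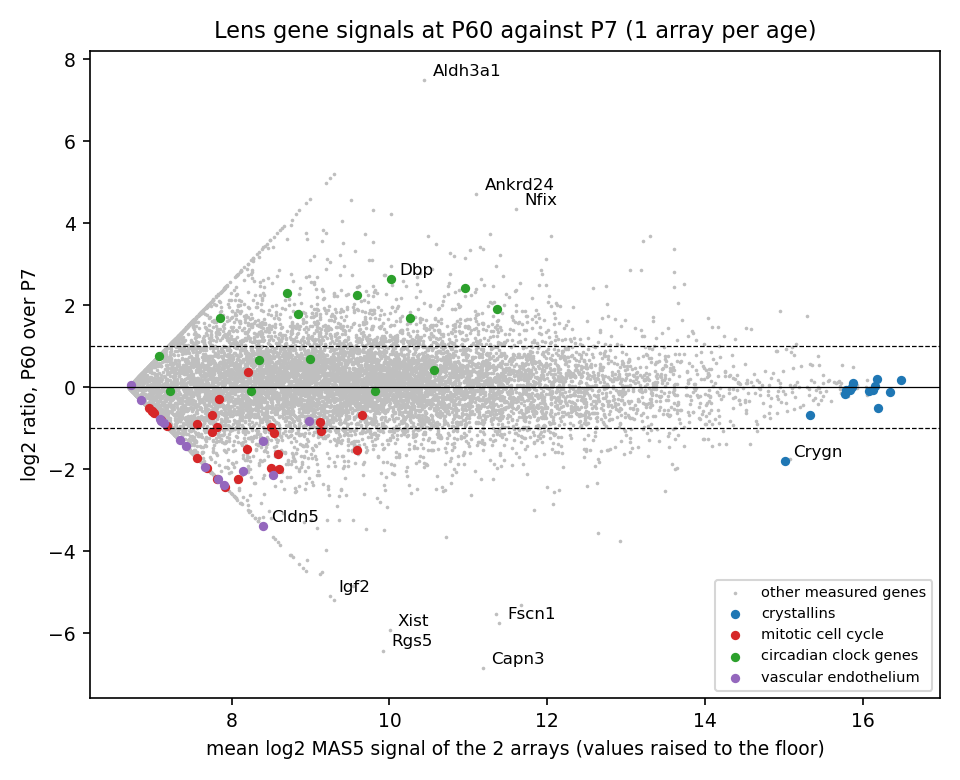
Log2 ratio of P60 over P7 (vertical axis) against the mean log2 MAS5 signal of the 2 arrays (horizontal axis), 1 point per measured gene, with 4 gene lists in colour and dashed lines at 2-fold. Crystallins sit at the bright end near a ratio of 0, while 13 of 27 mitotic genes lie at or below the lower dashed line and 8 of 15 clock genes at or above the upper one.

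The gene furthest below its P7 value, among genes above the floor on both arrays, was Capn3, which encodes a calcium-dependent protease of the calpain family. Its intensity was 25155 at P7 and 217 at P60, which is 116-fold lower, and its 2 probe sets had log2 ratios of -6.86 and -5.98. Rgs5, a regulator of G-protein signalling typical of pericytes, was 85.9-fold lower on the chosen probe set, with 4 probe sets from -6.43 to -2.19. Fscn1, which bundles actin filaments, was 54.1-fold lower with probe sets ranging from -5.76 to -1.07. Pla2g7, a secreted phospholipase, was 45.9-fold lower, and the connexin gene Gje1 was 39.9-fold lower (20552 against 515). Ednrb, an endothelin receptor, was 28.7-fold lower (probe sets from -4.84 to -2.16). Hmga2, a chromatin protein of fetal growth, was 22.8-fold lower on the chosen probe set, and its 4 probe sets ranged from -4.51 to -0.80. The efflux transporter Abcg2 was 18.6-fold lower. Xist and Rsad2 completed these 10 genes and are described with their groups. At P60 Rgs5 (104), Rsad2 (114), Abcg2 (115), Hmga2 (118), Xist (131) and Ednrb (138.79) read under the receptor 95th percentile of 138.86. The folds of these genes therefore rest on values near the floor and are close to bounds. Of genes detected at P7 only, Gask1b was at least 22.6-fold lower at P60 (its other probe set at -3.78), the membrane protein gene Cyyr1 at least 21.2-fold and the neuronal transcription factor Neurod1 at least 17.8-fold.

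At P60 the highest bound was that of Aldh3a1, an aldehyde dehydrogenase abundant in cornea, which was under the floor at P7 with 62.6 and reached 18639 at P60, at least 179-fold higher. It rests on 1 probe set. Also under the floor at P7 were Elmod1 (at least 36.9-fold higher), the growth factor Tgfb3 (at least 34.1-fold), the matrix protein gene Cilp (at least 31.6-fold) and Cubn, an endocytic receptor (at least 23.9-fold, its other probe set at 3.12). Among genes above the floor at both ages, Ankrd24 was 26.2-fold higher, with log2 ratios of 4.71 and 4.53 on its 2 probe sets. The transcription factor gene Nfix was 20.4-fold higher (692 at P7 and 14102 at P60), with its 4 measured probe sets from 1.41 to 4.35. Emp2 had a log2 ratio of 4.32, the highest of its 3 probe sets, which began at 1.57. The netrin gene Ntn4 was 18.6-fold higher (its other probe set at 0.78) and the lipase gene Abhd6 16.9-fold (its other probe set at 2.80). Tmem178 was 16.7-fold higher, Fam107a 15.6-fold (its other probe set at 2.13) and the metallothionein gene Mt2 14.3-fold. Abhd6 (106) and Fam107a (109) lay just above the floor at P7, so their folds are close to bounds.

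**Figure D2:**
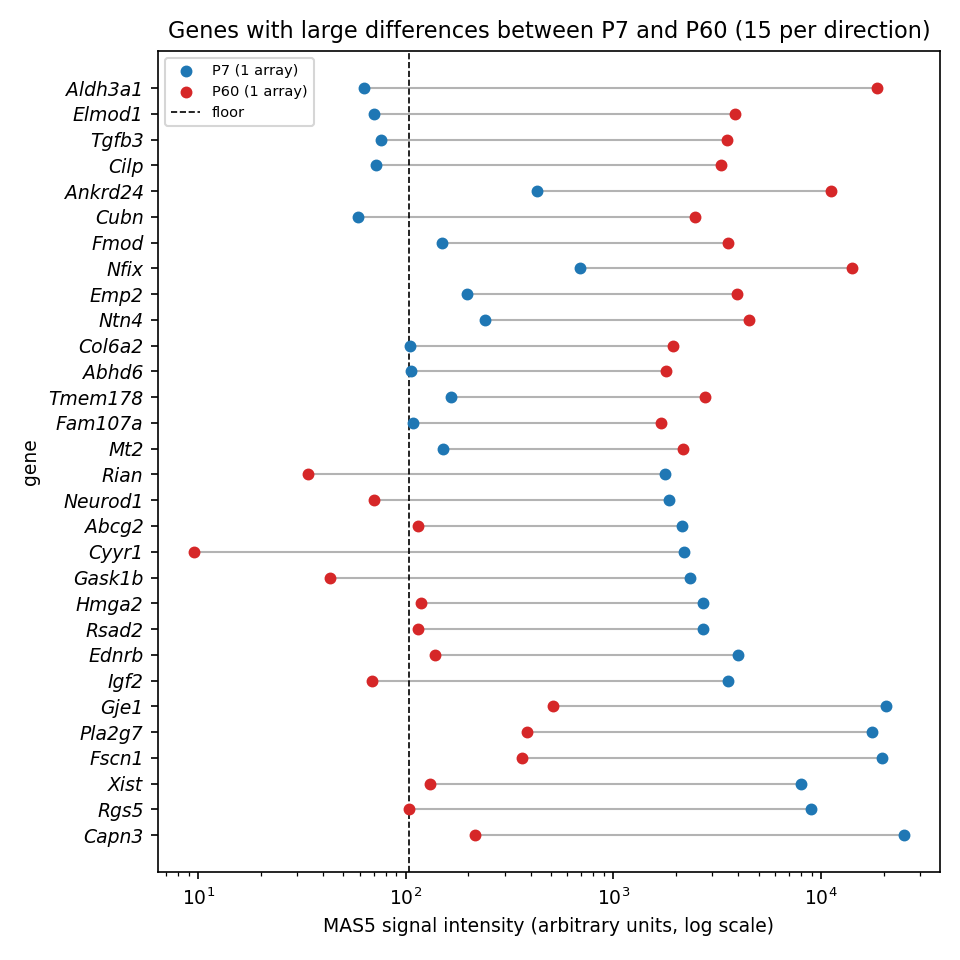
MAS5 signal intensity on a log axis at P7 (blue) and P60 (red) for 30 genes, in each direction the 10 largest ratios among genes above the floor on both arrays and the 5 largest bounds among genes above it on 1 array, 1 array per age, with the floor of 103.9 as a dashed line. Capn3 stands at 25155 and 217, and Aldh3a1 below the floor at P7 and at 18639 at P60.

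Crystallins, the structural proteins of the lens, had ratios near 0 on these arrays. Of 14 measured members 13 lay within 2-fold, with a median log2 ratio of -0.08 that ranged from -0.15 to 0.05 over the alternative settings. The α-crystallin gene Cryaa had a ratio of -0.08 and Cryab of 0.18, the latter with probe sets on both sides of 0. Among β-crystallins Crybb2 stood at 0.20, Crybb1 at 0.11, Cryba2 at 0.01, Crybb3 at -0.06, Cryba1 at -0.09 and Cryba4 at -0.17. Among γ-crystallins Crygd was at 0.02, Crygs at -0.08, Crygb at -0.12, Crygf at -0.50 and Cryga at -0.67. Crygn was the exception and was 3.47-fold lower at P60, with intensities of 61489 and 17708. The γ-crystallin genes are close in sequence, so their signals cannot be fully separated. Crystallin probe sets also lay near the top of the scale, where ratios of other genes spread less. Without crystallins, the SD of the log2 ratio was 0.38 over 158 probe sets with mean intensities from 32768 to 65536 and 0.13 over the 5 above that, against 0.92 over 6600 probe sets from 512 to 2048. The ratios near 0 at this level therefore do not exclude a difference between the ages.

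Genes of the fibre cell membrane and cytoskeleton were likewise mostly within 2-fold, 17 of 19 measured. Several lay near the top of the scale like the crystallins, such as Lim2 (56027 at P7), Bfsp1 (51940) and Mip (47008). Their ratios near 0 do not exclude a difference between the ages either. Aqp5, a water channel, was 10.2-fold higher at P60, and Caprin2, an RNA-binding protein, 13.5-fold lower (28567 against 2114). Clic5 had a log2 ratio of 0.81 and Slc24a4 of -0.76. Of 23 measured genes of the lens transcription factor list, which includes the receptor gene Notch2, 4 were 2-fold higher and 4 lower. Sox2 was 3.65-fold and Notch2 2.91-fold higher (its other probe set at 0.28), while Sox11 was 2.97-fold and Tfap2b at least 2.77-fold lower. Neither list stood apart from matched random lists.

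Ion channels, pumps and water channels were higher at P60 as a group: 13 of 21 were 2-fold higher and 2 lower, with a median log2 ratio of 1.14 and a percentile of 100. Besides Aqp5, the water channel Aqp1 was 5.50-fold higher. The calcium pump gene Atp2b1 and the pannexin gene Panx1 went the other way, 2.35-fold and 2.34-fold lower. Genes of the lens epithelium had a median of 0.84 (percentile 99.98), with 5 of 17 at least 2-fold higher, among them Aqp1 and Wls (2.90-fold, probe sets from 0.90 to 1.54), which is needed for Wnt secretion. Foxe3, an epithelial transcription factor, was 2.61-fold lower, and Slc38a3 had a ratio of -0.48. With the dimmest instead of the brightest probe set of each gene the epithelial median was 0.24 and the list no longer stood apart. Of 24 measured genes of the lens capsule and basement membrane, 7 were 2-fold higher and 4 lower (median 0.50, percentile 99.6). The type IV collagen gene Col4a3 was 5.15-fold higher (its other probe set at 1.72) and the prolyl hydroxylase gene P4ha1 3.09-fold higher (its other probe set at 0.71). Col18a1 was 2.88-fold lower, with its other probe set at -0.18, and Nid2 at least 2.44-fold lower. The call for this list was lost with the dimmest probe sets (median 0.09) and without the brightest 0.5% of genes (median 0.14).

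Genes of cell division were lower at P60. Of 27 measured mitotic genes 13 were at least 2-fold lower and none 2-fold higher, with a median of -0.97 and a percentile of 0. The cyclin gene Ccnb2 was at least 5.38-fold lower and Ube2c, a ubiquitin enzyme of mitotic exit, 4.73-fold lower. Plk1 had a ratio of -0.29 and Racgap1 of 0.37, the latter with its other probe set at -1.33. Of 28 DNA replication genes 6 were 2-fold lower and none higher (median -0.49, percentile 0.03). The thymidine kinase gene Tk1 was at least 4.07-fold and Rfc5, a clamp loader subunit, 3.86-fold lower, whereas Pola1 (0.76) and Lig1 (0.61) had ratios above 0. Vascular endothelial genes (median -1.32) and 3 globin probe sets (median -5.33) were lower in the same pool. Cyclin-dependent kinase inhibitors did not move together (median 0.15), although with the dimmest probe sets the list was called lower (median -0.685). Cdkn2b was at least 6.69-fold higher and Cdkn1c 3.92-fold lower, from 25468 to 6491, while Cdkn1b and Cdkn2d had ratios of 0.81 and -0.87, the former with probe sets on both sides of 0.

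Imprinted growth genes showed the lowest median of all lists, at -1.49 (percentile 0), with 9 of 13 at least 2-fold lower. Igf2, a growth factor expressed mainly before weaning in rodents, was 3573 at P7 and under the floor at P60, at least 34.4-fold lower. The non-coding RNA Rian was at least 17.1-fold lower (its other probe set at -2.93). Sgce was the only member higher, 4.30-fold, and Peg10 was close to the floor at P7 and under it at P60 (115 and 24.5). Vascular genes, with a median of -1.32, and the globin probe sets, from -7.04 to -5.21, were lower at P60 as well. Proteasome genes had a median of -0.55 (percentile 0), with 7 of 27 at least 2-fold lower and none higher, among them Psmb3 (2.85-fold lower, its other probe set at -0.67) and Psmb5 (2.76-fold lower). Psmd4 had a ratio of 0.28 and Psmc2 of 0.74, the latter with probe sets on both sides of 0.

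Clock genes had the highest median, 1.68, with a percentile of 100. Of 15 measured, 8 were at least 2-fold higher at P60 and none 2-fold lower. Dbp, a clock output factor, was 6.22-fold higher on the chosen probe set, and its 2 probe sets had ratios of 2.64 and 2.76. Tef, its relative, was 5.37-fold higher, with its dimmest probe set at 0.18. Arntl, which encodes the activator BMAL1, and the repressor gene Cry2 both had ratios of -0.10. Genes of the interferon response and antigen presentation were also higher (median 0.75, percentile 99.99), with 6 of 20 at least 2-fold higher. Ifi27 was 13.4-fold (its other probe set at 2.91) and Gbp2 at least 5.38-fold higher, but Rsad2, an antiviral enzyme, was 23.6-fold lower, with its 3 probe sets between -4.56 and -3.03, and Psmb9 lay near the floor at P7 and under it at P60 (126 and 79.2).

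**Figure D3:**
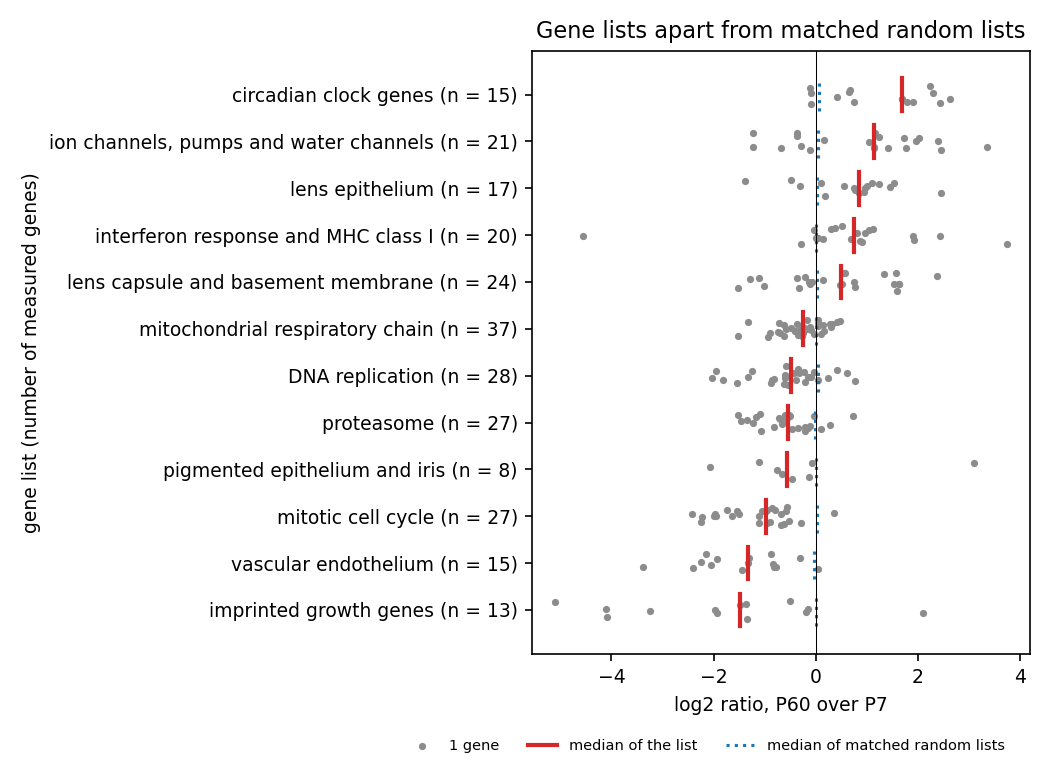
Log2 ratio of P60 over P7 (horizontal axis) for the genes (grey points) of the 12 lists whose median (red bar) stood outside the central 95% of matched random lists (dotted blue bar, their median), 1 array per age. Clock genes and ion channels have the highest medians, at 1.68 and 1.14, and imprinted growth genes and vascular endothelium the lowest, at -1.49 and -1.32.

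Markers of cells other than lens cells differed in their behaviour. Of 15 vascular endothelial genes 9 were at least 2-fold lower at P60 and none higher (median -1.32, percentile 0). Most of them were under the floor at P60, so their ratios are bounds and the floor holds the median in. It ran from -2.145 to -1.243 over the settings. The tight junction gene Cldn5 was at least 10.5-fold and Esam at least 5.26-fold lower, while Flt1 (128 at P7 and 95.8 at P60) and Erg (49.8 and 107, with probe sets on both sides of 0) were close to the floor and above it on 1 array only. Of the erythroid list only 2 genes were measured on probe sets of their own, both under the floor at P60, so that their ratios are bounds: Hba-a2 was at least 1.72-fold lower (179 against 18.9) and Hbb-b2 at least 1.67-fold (173 against 5.96). Probe sets shared by several globin genes were brighter, and 3 of them had ratios from -7.04 to -5.21. Pigment cell genes had a median of -0.56 (percentile 2.35), with Tyrp1 4.20-fold (probe sets from -2.07 to -0.55) and Pmel 2.15-fold lower, Mlana near the floor at P7 and under it at P60 (110 and 53.2) and Oca2 8.62-fold higher. This call was lost under 7 of the 13 alternatives run. Of 14 macrophage and leukocyte genes, most of them near the floor, 12 did not reach 2-fold, with Cd74 2.93-fold higher, Fcer1g at least 2.10-fold lower, Cd163 at least 1.58-fold higher and Mrc1 at least 1.67-fold lower. Photoreceptor and retinal genes went both ways. Pdc was 4.44-fold and Nrl 3.25-fold lower, Gnat1 was at least 7.59-fold and Glul 3.46-fold higher, and the median was -0.02 with a mean of 0.05. Connective tissue genes also split, with Fmod 23.7-fold (probe sets from 2.44 to 4.57) and Col6a2 18.6-fold higher (105 at P7, near the floor, and its other probe set at 2.34). Fbn2 was 15.7-fold (its other probe set at -3.33) and Mgp at least 5.45-fold lower, and the median was 0.07. Among 7 measured genes of the corneal list only Aldh3a1 passed 2-fold, and the corneal keratin Krt12 was under the floor on both arrays. Krt6a was at least 1.74-fold lower (181 at P7 and 31.8, under the floor, at P60), and Upk1b (0.01) and Dsc2 (0.66) had probe sets on both sides of 0. Of 16 skeletal muscle genes 5 were measured (median -0.02, mean 0.14), with Actn3 2.05-fold higher and Mylpf at 0.35. Tnni2 and Pvalb were under the floor at P60 and at least 1.22-fold and 1.28-fold lower (127 against 13.8 and 133 against 11.2).

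Of 4 measured sex-linked transcripts 2 were at least 2-fold lower (median -0.58, percentile 6.19). The list mixes Xist with Y-linked genes, which a difference in sex make-up would move in opposite directions. Its median and percentile, in this or any other setting, therefore do not describe a shared shift. Xist, the RNA that silences 1 X chromosome in female cells, was 60.9-fold lower at P60 (8002 against 131), and its 3 probe sets had ratios from -5.93 to -4.24. The ratios of -4.24 and -5.67 are bounds, as these probe sets were under the floor at P60 (8.28 and 11.3). Of the Y-linked genes Eif2s3y was 2.82-fold lower, while Kdm5d and Uty had ratios of 0.38 and 0.35, the latter with probe sets on both sides of 0.

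Metabolic and stress genes showed smaller shifts of their lists. Respiratory chain genes had a median of -0.26 (percentile 2.17), with 2 of 37 at least 2-fold lower, Ndufs3 (2.87-fold) and Uqcrc2 (2.49-fold), while Ndufb10 and Atp5d had ratios of 0.47 and 0.42. This call was lost under 5 of the 13 alternatives. Of 31 antioxidant genes 9 were 2-fold higher and 4 lower (median 0.30, percentile 96.2). This list was called higher without a floor (0.386), with the mean over probe sets (0.267), without shared sequence (0.509) and without the brightest genes (0.346). Gpx3, a secreted glutathione peroxidase, was 12.8-fold higher and Mgst1 5.62-fold higher, while Gpx1, the cytosolic enzyme, was lower at P60 (25178 against 6294) and Hmox1 2.42-fold lower. In glycolysis, 3 of 19 genes were 2-fold higher and 1 lower. Aldoa was 3.07-fold (probe sets from 0.91 to 1.62) and Pfkp 11.4-fold higher, the latter with another probe set at -0.42, and Slc16a1, a lactate transporter, was 2.83-fold lower, with Bpgm at -0.58. Cholesterol synthesis genes had a median of -0.02, with Insig1 3.15-fold and Dhcr7 2.39-fold higher, Msmo1 2.34-fold lower and Idi1 2.35-fold lower (its other probe set at -0.34). Chaperone genes had a median of 0.06. The inducible Hspa1b was 5.51-fold higher (probe sets from 2.46 to 3.62) and Hspa1a had a ratio of 1.32, with Dnaja1 3.66-fold lower with 1 probe set on the other side, and Cct3 at -0.97 (probe sets from -2.08 to -0.65). Hspa1a and Hspa1b are near-identical, so their signals cannot be separated with certainty. Autophagy genes had a median of -0.003 and a mean of 0.05, with Pink1 2.96-fold and Map1lc3a 2.99-fold higher, the latter with another probe set at 0.60. Atg5 was 3.02-fold lower on the chosen probe set (range -1.59 to -0.13) and Map1lc3b 2.22-fold lower (range -1.15 to -0.18). Without probe sets marking shared sequence, within a gene or between genes, Atg5 stood at -0.13, Map1lc3b at -0.64 and Map1lc3a at 0.60. The chosen Map1lc3b probe set was of the kind shared within a gene. Ribosomal protein genes had a median of -0.12, with Rps25 3.84-fold and Rpl14 2.13-fold lower and Rps27 and Rps15 at 0.35 and 0.32.

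Adhesion, membrane skeleton and signalling lists did not stand apart from matched lists in the main setting. Among 17 junction genes Arvcf was 4.68-fold higher (its dimmest probe set at 0.09) and Ctnna2, which encodes αN-catenin, 2.79-fold higher, Cdh11 was at least 9.09-fold lower and Ctnnd2 stood at -0.71 (median 0.39, percentile 95.5). Of the membrane skeleton genes Ank1 was 5.84-fold and Epb41l3 2.94-fold lower (the latter with probe sets from -1.55 to -0.97), with Add3 and Utrn at 0.93 and 0.84 (lowest probe sets at 0.01 and 0.19; list median 0.03, mean -0.16). In FGF signalling, Fgf1 was 8.54-fold higher (its other probe set at 2.10), Ptpn11 2.13-fold higher with 1 probe set on the other side, Shc1 4.31-fold lower (its other probe set at -0.45) and Spry4 at least 2.23-fold lower (median 0.39, percentile 90.1). In the Notch, Wnt and TGF-beta list, Notch3 was 3.85-fold lower (its other probe set at -0.88) and the inhibitor Id2 3.53-fold lower (probe sets from -1.82 to -0.63), with Tgfb2 at 0.75 (median -0.12). Immediate early genes, which respond to tissue handling, had a median of 0.32 (percentile 93.3), with Fos 2.82-fold and Egr1 2.03-fold higher, Klf2 at least 2.62-fold lower and Zfp36 at -0.93. This list was called higher with the 75th percentile floor (median 0.686), without a floor (0.682) and with the pseudocount (0.501). Egr1 no longer passed 2-fold with the pseudocount (0.79), median centring (0.95) or loess (0.999), nor did Klf2 with the floor at the 95th percentile of the receptor probe sets (-0.97). Of the other genes named, Actn3, Atp2b1, Fcer1g, Foxe3, Hspa1a, Nid2, Panx1, Pmel, Rpl14, Sox11 and Spry4 no longer passed 2-fold under at least 1 alternative for the floor, the pseudocount or the scaling.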

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

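The tests of non-lens tissue as a whole, of blood, of a single faulty Xist probe set, of the share of male lenses and of the time of day were chosen after the results were seen. The test with a second endothelial set was chosen earlier, although its member Cyyr1 had been seen.

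Several signals came from probe sets outside the comparison. A control probe set for the B1 repeat, a short interspersed element, was 32.7-fold lower at P60 (46162 against 1410). The 6 probe sets of the bioB hybridisation control, a bacterial transcript added to the sample, had a median log2 ratio of 2.65 (from 2.24 to 3.20), while those of the controls bioC, bioD and cre ranged from -0.64 to 0.35. The 3 globin probe sets over 10 times the floor, each annotated to several globin genes, had a median log2 ratio of -5.33 (from -7.04 to -5.21). A probe set annotated to H19 and to the microRNA gene within it was at least 33.8-fold lower at P60. Among 2798 measured probe sets without a gene symbol, 189 were at least 2-fold higher and 219 at least 2-fold lower at P60.

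Vascular genes were lower at P60. Whether there was less tissue of every non-lens type in the P60 pool cannot be told from these values. Of the 6 other non-lens lists 5 had a percentile of 10 or more, with many genes near the floor, and pigment cell genes were at 2.35. The 32 genes of these lists bright enough at either age to show a difference of the vascular size had a median log2 ratio of 0.082. That was above the vascular median of -1.32 by less than their SD of 2.35. This choice takes in genes bright only at P60, such as Aldh3a1 (62.6 and 18639) and Gnat1 (12.8 and 789), which pull the median up. It also takes in genes bright only at P7, such as Fbn2 (2327 and 148) and Mgp (566 and 10.4), which pull it down. The median therefore cannot decide the question. Fewer vessel cells in the P60 pool is a candidate explanation: in the second endothelial set 9 of 23 measured genes were at least 2-fold lower and 2 higher, at percentile 0, or 0.04 without Cyyr1. Blood left on the P7 lenses was considered because of the globin values, which therefore cannot test it: of 5 listed erythroid genes other than globins 0 were measured, and the macrophage and leukocyte genes, most of them near the floor, had a percentile of 25.9. Regression of the vessels around the lens with age and a difference in dissection both remain open, because age and pool cannot be separated with 1 pool per age.

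Xist was lower at P60. A fault of 1 probe set is argued against, because all 3 of its probe sets had ratios of -4.24 or lower. At P60 they read 8.28, 11.3 and 131, and the ratios of those under the floor are bounds. A larger share of male lenses in the P60 pool could account for it, but the Y-linked genes were divided, with a median of 0.35 from Eif2s3y at -1.50, Kdm5d at 0.38 and Uty at 0.35. These Y-linked genes read 528, 387 and 227 at P60 and 1490, 297 and 178 at P7, all above the floor. At P60, then, Y-linked genes were read while Xist was near or under the floor, the pattern of male tissue, whereas at P7 both were read. A difference in the sex make-up of the pools is thus confounded with age. The values cannot tell the 2 apart, for Xist or any other gene here. The sex of the animals is not given in the sources used here.

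Clock genes were higher at P60. A different time of day at collection might shift them, and would move genes opposite in phase to Dbp the other way. Those genes had a median of 0.42, with Arntl at -0.10, Clock at 0.42 and Nfil3 at 1.19, a value between the limits set for either outcome. Time of day and age cannot be told apart here, since the hour of collection is not given in the sources used here.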

How the results depend on the processing

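The floor at the 95th percentile of the receptor probe sets was chosen after the data were seen. A floor at the median of all values was the main setting and was not run again, and no paired analysis was possible because each age had 1 array. Of the 12 lists called apart, 8 kept their call in all settings run (mitotic, DNA replication, vascular, imprinted, ion channels, interferon, clock and proteasome). The median log2 ratio of all genes was -0.003 with the floor at the 75th percentile of the receptor probe sets, 0.04 at their 95th percentile, -0.036 without a floor, -0.04 with median centring, 0.045 with quantile normalization, 0.059 with loess, 0.136 with centring on ribosomal protein genes (which removes a median of -0.125), -0.022 with the mean over probe sets, 0.007 without probe sets marking shared sequence and -0.065 with the dimmest probe set. Genes higher and lower numbered 2761 and 3627 without a floor (a setting that also changes the pseudocount and the genes counted), 2960 and 2622 at 1.5-fold, and 272 and 192 at 4-fold. The pigment cell list lost its call at -0.477 (95th percentile floor), -0.455 (pseudocount), -0.575 (quantile), -0.297 (mean over probe sets and dimmest probe set), -0.65 (no shared sequence) and -0.557 (without the brightest genes). The respiratory chain lost its call at -0.25 (mean over probe sets), -0.233 (no shared sequence), -0.2 (dimmest), -0.221 (without the brightest) and -0.257 (unmatched random lists). The lens epithelium lost it at 0.236 (dimmest), and the capsule at 0.088 (dimmest) and 0.144 (without the brightest). Calls were gained by the erythroid list at -1.412 with 3 members and immediate early genes at 0.686 (75th percentile floor), by corneal genes at 0.663, antioxidant genes at 0.386 and immediate early genes at 0.682 (no floor), by immediate early genes at 0.501 (pseudocount), by antioxidant genes at 0.267 and Notch, Wnt and TGF-beta genes at -0.334 (mean over probe sets), by antioxidant genes at 0.509 (no shared sequence) and 0.346 (without the brightest), and by kinase inhibitors at -0.685 and sex-linked transcripts at -0.884 (dimmest). With the dimmest probe set Pfkp (-0.371), Dnaja1 (0.344) and Ptpn11 (-0.163) were reversed, and Racgap1, under 2-fold before, stood at -1.328. The cause was not tested for these changes. Of the 1494 higher and 1230 lower genes, 990 and 884 were shared with the dimmest probe set and 1092 and 850 with the pseudocount. Of 162 named genes, those that no longer passed 2-fold numbered 19 with the dimmest probe set besides the 3 reversed, 11 with the pseudocount and 8 with the mean over probe sets, and 6 of 138 did so without shared sequence. The named genes include many under 2-fold in the main setting, so the share lost among the 2-fold genes is larger than these totals give. Values near the floor limit what low signals can show.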

Other observations

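The tests with the fetal growth, contractile and glucocorticoid lists were chosen before their percentiles were computed, although Hmgb2 and Acta2 had been seen. The other genes named here were chosen after their values were seen.

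The metallothionein genes went apart, with Mt1 7.99-fold lower (10282 at P7 and 1287 at P60, its other probe set at -2.30) while Mt2 was 14.3-fold higher. Pdgfrb and Rgs5, both associated with pericytes, also went apart. Pdgfrb was 9.72-fold higher on the chosen probe set (2.04 on the log2 scale on the other) and Rgs5 85.9-fold lower (104 at P60, next to the floor, with probe sets from -6.43 to -2.19). No list of pericyte genes was compared. A probe set annotated to Cryga and an unnamed transcript was 76.2-fold lower, whereas the probe set of Cryga alone had a log2 ratio of -0.67.

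Imprinted growth genes may be part of a wider fetal growth programme that is lower at P60. A second list of such genes had a median of -0.83 at percentile 0.04, and 0.14 without Hmgb2, with 6 of 15 measured genes at least 2-fold lower and none higher. Several of its genes are also linked to proliferation, and the mitotic list was lower as well (median -0.97, percentile 0). Without the 5 such genes Hmgb2, Trip13, Ezh2, Hells and Dnmt1, a choice made after the values were seen, the median was -0.66 at percentile 0.68, and without the first 3 alone it was -0.28 at percentile 7.17. Growth and cell division are therefore not separated here, and the vascular genes (median -1.32, percentile 0, with the second endothelial set also at percentile 0) and the globin probe sets (-7.04 to -5.21) were lower in the same pool. Hmgb2 was 9.50-fold lower, Igf2bp3 5.60-fold (probe sets from -3.48 to -1.31), Igf2bp1 4.01-fold (from -2.94 to -1.001), Trip13 3.44-fold and Mycn 2.01-fold (its other probe set at -0.31), and Ezh2 had a log2 ratio of -1.58.

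Acta2, which encodes smooth muscle actin, was 11.8-fold higher at P60 on the chosen probe set, and its other probe set had a log2 ratio of 1.60. Contractile genes as a group might be higher too, but their percentile of 97.07 (median 0.45) lay between the limits set, and without Acta2 it was 88.8. Tpm1 was 2.36-fold higher (its other probe set at 0.93).

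Glucocorticoid-induced genes were higher as a group, with a median of 0.58 at percentile 99.31. A hormonal contribution to the higher clock genes is a hypothesis only, which these arrays cannot tell from age or time of day. Of 14 measured genes 4 were at least 2-fold higher and none lower: Lcn2 at least 3.41-fold, Sgk1 2.60-fold, Klf9 2.26-fold (with probe sets on both sides of 0) and Errfi1 2.21-fold (its other probe set at 0.37). The 10 others lay between 0.03 (Tsc22d3) and 0.91 (Angptl4). Among them Tsc22d3, Fkbp5 (0.49) and Zbtb16 (0.32) had probe sets on both sides of 0. Pdk4 (0.18) and Map3k6 (0.04) were under the floor at P7.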
